A study of Homo sapiens with 42 samples.

How the data were processed

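Total RNA of 42 samples of HES3 cells was extracted with the RNeasy Plus Micro kit, amplified from 100 ng with the Illumina TotalPrep kit into biotin-labelled cRNA and hybridised to 1-colour Illumina BeadChips, per the labels' protocols. The RNA amplification starts from poly(A) priming, so signal near the 3' end of transcripts is favoured. Groups were taken from the culture condition and culture day in the labels.

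The deposited tables held, per the file headers, the raw signal intensity of 48803 probes with a detection p-value for each array, the same intensity after BeadStudio background subtraction, the signal of 759 negative and 25 other control probes, and variance-stabilised, quantile-normalised values on a log2 scale. BeadStudio and lumi are named in the submitters' processing notes, and their versions are not given in the sources used here. Raw minus background-subtracted intensity equalled the mean of the negative controls within 0.0103 on each array. The authors' log2 values came as series values for all 48803 probes and as a separate filtered table. That table covered only the 19052 probes with a detection p-value under 0.01 on at least 1 array. On these probes it was identical to the series values (largest difference 0). Each array of these values had a median of 7.35, values ran from 7.14 to 15.2, and they were not centred by probe. Group means ranked probes as the raw log2 intensity did (Spearman's rho at least 0.999 with the same group and at most 0.969 with any other). By Pearson's r, 17 of 18 groups matched their own raw log2 intensity best, and EB medium at day 7 matched BCM at day 7 slightly better (0.982 against 0.977). This transformation compresses changes of dim probes, so fold changes from it are smaller.

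Columns of the raw tables carry a group name with a code of 2 digits and a letter, and no replicate number, so they were used as unnumbered replicates. Only the authors' log2 values carry the replicate numbers of the labels. There are 8 codes, which hold 1 to 6 arrays each and look like chip numbers, but the labels do not say so. They are called array codes and were treated as a possible batch. All 3 arrays of EB medium with Matrigel at day 14 share code 59, with undifferentiated cells and EB medium without and with Matrigel at day 90.

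Raw intensities were corrected and normalised with limma 3.58.1 in R 4.3.3 (neqc: normexp background correction from the negative controls, offset 16, quantile normalisation, log2). The 18309 probes with a detection p-value under 0.01 on at least 2 arrays were tested. A mean per group was fitted over all 42 arrays with 1 residual variance per probe (24 residual degrees of freedom), moderated with eBayes (prior degrees of freedom 3.75), and p-values were adjusted by the Benjamini-Hochberg method over probes within each comparison, with a call at adjusted p under 0.05. The median residual SD was 0.13 log2 units. Counts of calls of at least 2-fold are given beside the counts with no minimum, because replicates were so close that very small differences pass the test.

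The position of an array between undifferentiated cells and day 90 is the projection of its tested probes on the line between these means, and it was tested by turning the sign of differences between group means exactly. It was defined after the data were examined. Overlap between media used comparisons with no group in common, and the expected overlap is that of independent lists per direction.

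The rule for naming, fixed before the data were examined, took pluripotency genes, members of called gene lists and the 10 largest rises and falls among called genes of each comparison. None of the 48803 probe identifiers was paired with a gene in the files or matched the gene table used here. Of 40 gene lists fixed beforehand (cell types, pathways and stress), 0 were tested, and of the rule only the 2 largest rises and 2 largest falls at day 90 against undifferentiated cells are printed, by probe identifier. A probe undetected on all arrays of a group has only a bound there.

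The model was tested on simulated arrays with the real probe means and residual SDs, in which 50 of 18309 probes were changed by each of 4 folds. For day 90 against undifferentiated cells, 24% of 1.2-fold, 86% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes were recovered and 7 unchanged probes were called. For Matrigel over 6 pairs these were 64%, 100%, 100% and 100% with 12 unchanged probes called. The simulated noise was independent between arrays, whereas real residuals of arrays sharing a code correlated at a mean of 0.272. The numbers of unchanged probes called hold only without such dependence. So few changed probes make the Benjamini-Hochberg cut stricter than where many probes change. Recovery may be understated for such comparisons, also in the tests with group means as replicates.

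Alternatives were no background correction, BeadStudio background subtraction with values under 16 set to 16, an offset of 50, median scaling, cyclic loess, the authors' log2 values, no detection filter, detection on at least 10 arrays, the array code as a block, only the groups compared, array weights, eBayes with trend and robust options, and leaving out each array in turn. The replicate number as a block could be fitted only to the authors' log2 values. Added after seeing the data were that source of values for the block, group means as replicates, and comparisons without day 14, without EB medium with Matrigel at day 14 and without BCM at day 14. Figures were drawn with matplotlib 3.10.9.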

Results

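Expression was measured in cells of HES3, an established human embryonic stem cell line, before differentiation and after growth as embryoid bodies, the aggregates in which pluripotent cells differentiate into many cell types. Embryoid bodies were kept in embryoid body (EB) medium or in bulk conditioned medium (BCM), each with or without Matrigel, a gelled basement membrane extract, and were harvested at days 7, 14, 30, 60 and 90. The series title names a 3-dimensional in vitro counterpart of the teratoma assay, so the comparisons ask how expression moves away from the undifferentiated state with time and how medium and Matrigel alter that course. The 42 arrays fall into 18 groups. Undifferentiated cells, EB medium at days 7, 14 and 30, and EB medium with Matrigel at days 7, 14, 30 and 90 have 3 arrays each. EB medium at day 90, BCM at days 7, 14 and 30, and BCM with Matrigel at days 7, 14, 30 and 90 have 2 each, and the groups at day 60 have 1 each. Nothing in the labels says whether replicates came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. The files identify probes by number and do not pair them with genes, so changes are reported by probe and 4 probes are named in all.

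Between 11921 and 15433 of the 48803 probes were detected per array, and mean raw signal ranged from 222 to 740 intensity units. BCM at day 14 was the dimmest group, with a mean signal of 246 ± 33.6 (SD, n = 2) and a housekeeping control signal of 7945 ± 996, against 435 ± 84.6 and 15161 ± 3155 (n = 3) in EB medium on the same day. Replicates lay close together. Over the 32 pairs of arrays within a group, the SD of the log2 difference across 18309 tested probes was 0.14 to 0.38, whereas means of different groups were 0.27 to 1.60 log2 units apart (root mean square).

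Groups at day 90 lay far from undifferentiated cells, and earlier groups were not all on the way between them. The first principal component carried 51.5% of the variance and the second 10.8%. On the first, undifferentiated cells were at -57.3 and the day 90 groups at 105 to 113, while all day 7 groups (-72.7 to -64.3), BCM at day 14 (-67.4) and EB medium with Matrigel at day 14 (-69.0) lay on the side away from day 90. Each array was also placed on the line from the undifferentiated mean (0) to the mean of the 3 groups at day 90 (1), where noise in the undifferentiated mean would by itself put an unchanged group at 0.00516. All 4 conditions were close together at day 7, at 0.129 ± 0.00453 (SD, n = 3) in EB medium, 0.147 ± 0.00858 (n = 3) in EB medium with Matrigel, 0.131 ± 0.00994 (n = 2) in BCM and 0.129 ± 0.0152 (n = 2) in BCM with Matrigel. They had spread out by day 30, to 0.652 ± 0.00606 (n = 3), 0.792 ± 0.00364 (n = 3), 0.467 ± 0.00532 (n = 2) and 0.369 ± 0.00162 (n = 2) in the same order. At day 90 the 3 groups measured lay within 0.989 to 1.01 of the scale, which they define.

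**Figure D1:**
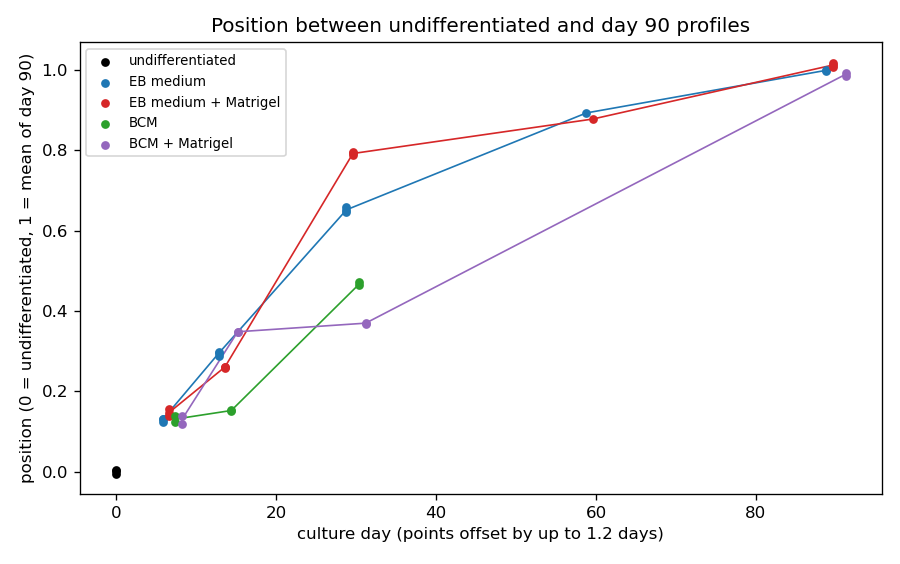
Position of each array between the undifferentiated mean (0) and the mean of the day 90 groups (1) against culture day, with points for arrays and lines through group means; points of different conditions are offset sideways. At day 30 the groups in EB medium lie at 0.652 and 0.792 and those in BCM at 0.467 and 0.369.

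**Figure D2:**
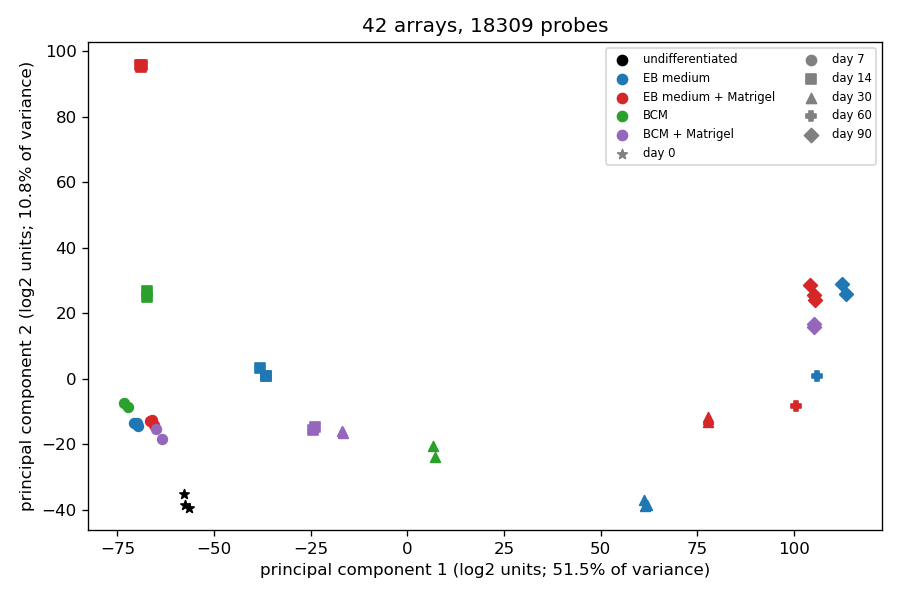
First and second principal components of 18309 probes on 42 arrays, in log2 units, with colour for condition and symbol for culture day. The 3 arrays of EB medium with Matrigel at day 14 lie at 95.6 on the second component, apart from all other groups.

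Changes from undifferentiated cells grew with time. Averaged over the conditions of a day, 1944 probes had changed at least 2-fold at day 7 (1352 higher and 592 lower), 2749 at day 14 (1461 and 1288), 3779 at day 30 (2079 and 1700) and 6595 at day 90 (3316 and 3279). Day 90 averages 3 conditions and lacks BCM without Matrigel, where the other days average 4. Averaging also lowers counts where conditions diverge, since 2749 at day 14 is below the count of each single group of that day. By group, the day 7 counts were 1600 higher and 986 lower in EB medium, 1548 and 957 in BCM, 1517 and 641 in EB medium with Matrigel and 1071 and 461 in BCM with Matrigel. With no minimum fold, limma called 11726 of 18309 probes at day 7 (5285 higher and 6441 lower, adjusted p under 0.05), 13026 at day 14 (6178 and 6848), 13829 at day 30 (6739 and 7090) and 14856 at day 90 (7052 and 7804). Which direction had more of these calls depended on scaling, since day 14 had 7892 higher and 6398 lower under median scaling and 6951 and 6181 under cyclic loess, which also gave 7223 and 6757 at day 30 and 7637 and 7359 at day 90. With the array code, the 2 digits that column names share, as a block, the counts were 12261, 12485, 13053 and 15297. When each condition mean was taken as 1 replicate, the counts were 10817, 4436, 8312 and 9776. The differences of a day share the undifferentiated mean, whose error does not enter these counts. Single groups did not follow the order of days in every condition. EB medium with Matrigel at day 14 had 5411 probes changed at least 2-fold, close to its 5563 at day 30, while EB medium, BCM and BCM with Matrigel had 3053, 3133 and 2993 at day 14. In BCM the count hardly grew from day 14 to day 30, at 3208, and BCM with Matrigel had 2828 at day 30.

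**Figure D3:**
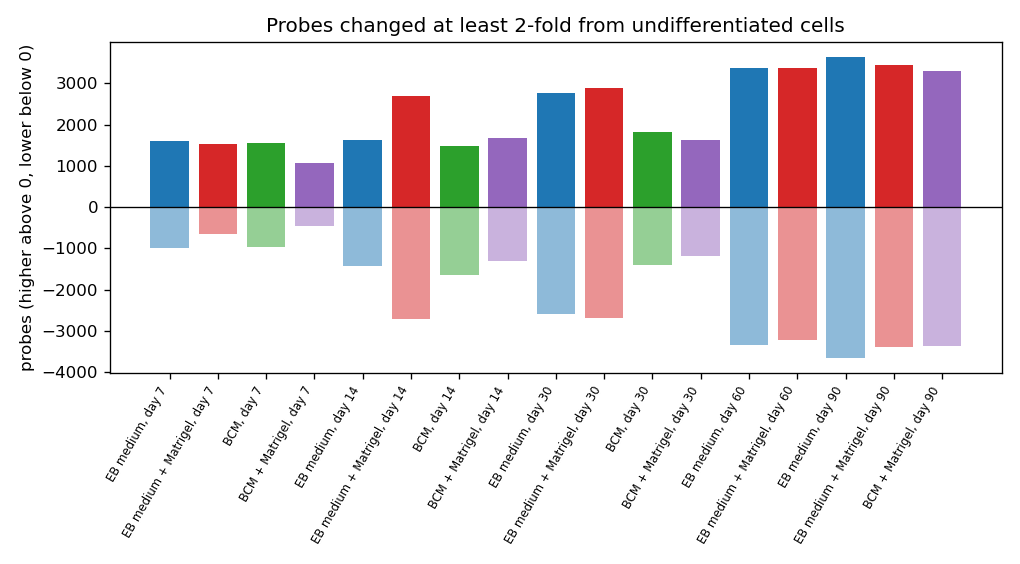
Number of probes at least 2-fold higher (above 0) or lower (below 0) than in undifferentiated cells, by group, at adjusted p under 0.05; the single arrays at day 60 were not tested and show all probes at least 2-fold apart. EB medium with Matrigel at day 14 has 2694 higher and 2717 lower probes, more than the other groups of that day.

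The probes with the largest changes at day 90 crossed the detection limit. ILMN_2198912 was 10.14 ± 0.08 (SE) log2 units higher at day 90 than in undifferentiated cells (7 and 3 arrays, limma adjusted p = 3.89e-37), and ILMN_1729801 was 9.99 ± 0.05 higher (adjusted p = 9.2e-42). Neither was detected in undifferentiated cells, so the folds are bounds of at least 369-fold and at least 299-fold, taken against the lowest signal of a detected probe on each array. ILMN_1748903 fell by 9.31 ± 0.06 (adjusted p = 3.15e-38) and ILMN_1679060 fell by 8.83 ± 0.06 (adjusted p = 1.73e-38), from detection on 3 of 3 undifferentiated arrays to 0 of 7 at day 90, at least 229-fold and 240-fold lower.

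These 4 probes did not change at the same time. ILMN_2198912, at 4.80 ± 0.09 log2 units (SD, n = 3) in undifferentiated cells, was detected at day 7 only in BCM (7.80 ± 0.34, n = 2). At day 14 it stood at 14.11 ± 0.06 (n = 3) in EB medium, 8.34 ± 0.06 (n = 3) in EB medium with Matrigel and 10.81 ± 0.10 (n = 2) in BCM with Matrigel, and it was undetected in BCM. ILMN_1729801 was undetected in all groups at days 7 and 14 and reached 13.61 ± 0.09 (n = 3) in EB medium with Matrigel and 11.91 ± 0.10 (n = 3) in EB medium at day 30. The BCM groups had it too, since it was detected on 10 of 10 arrays of that day, with a mean of 12.06 over the 4 conditions. ILMN_1748903 stayed at 13.08 ± 0.12 (n = 2) in BCM and 13.35 ± 0.05 (n = 2) in BCM with Matrigel at day 30, when it was at 8.78 ± 0.14 (n = 3) in EB medium and undetected in EB medium with Matrigel. ILMN_1679060 showed the same order, at 11.87 ± 0.13 and 13.28 ± 0.03 (n = 2 each) in BCM without and with Matrigel, 8.44 ± 0.03 (n = 3) in EB medium and no detection in EB medium with Matrigel.

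Between days 7 and 30, 3025 probes changed at least 2-fold (1760 higher and 1265 lower, averaged over 4 conditions). Between days 30 and 90, 2598 did (1475 and 1123, averaged over the 3 conditions measured at day 90). Counts with no minimum fold were 14793 (6997 higher and 7796 lower, or 7465 and 7382 under cyclic loess) and 13492 (5941 and 7551), or 13467 and 13137 with the array code as a block. With condition means as replicates the first was 4634. The second was 0, with 3702 probes at an unadjusted p under 0.05 in limma. That test recovered 0% of simulated 4-fold changes over its 3 differences. Few probes were changed in the simulation, which makes the adjustment stricter, so the 0% cannot account for the 0 calls. With 3 differences the same test called 9776 probes at day 90 against undifferentiated cells. Of the 3316 probes that were at least 2-fold higher at day 90 than in undifferentiated cells, the median probe had made 2.36% of its change in EB medium at day 7, 17.6% at day 14 and 54.4% at day 30. With Matrigel in EB medium the median reached 76.4% at day 30, and in BCM it was 45.5% without and 33.1% with Matrigel. For the 3279 probes that fell, the median was 17.6% in EB medium at day 7 and 71% at day 30. At day 30 it was 79.7% with Matrigel in EB medium, 44.9% in BCM and 36% in BCM with Matrigel. Other changes did not last. At least 2-fold above both undifferentiated cells and day 90 were 671 probes at day 7, 516 at day 14 and 238 at day 30, and at least 2-fold below both were 189, 265 and 76.

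Groups with and without Matrigel differed in many probes at each day, but the difference averaged over days and media was small. Averaged over the 6 pairs of groups at days 7, 14 and 30, 76 probes differed at least 2-fold (60 higher and 16 lower with Matrigel), and limma called 9623 with no minimum fold (4680 and 4943, or 4794 and 4559 under cyclic loess), or 10879 with the array code as a block. With the 6 pair differences as replicates, limma called 0 probes, with 814 at an unadjusted p under 0.05, fewer than that threshold gives by chance. Simulated 2-fold and 4-fold changes were recovered there in 46% and 82% of cases, with few probes changed in the simulation. The difference had the same direction in all 6 pairs for 3.79% of probes, against 3.12% expected of 6 independent pairs. Pairs of the same day were not independent (r = 0.604 at day 7), so the 3.12% is not a firm baseline. Of the 32 ways to turn the direction of pairs, 18 called at least as many probes as the real one and 22 at least as many of 2-fold or more (highest other 301). Single pairs differed far more. In EB medium, 561 probes changed at least 2-fold with Matrigel at day 7, 3876 at day 14 and 1558 at day 30, and in BCM 348, 2717 and 492 did. Within single array codes the numbers were 603 and 557 (EB medium, day 7), 401 and 456 (BCM, day 7), 2960 and 2755 (BCM, day 14) and 576 and 569 (BCM, day 30), and no code held both groups of EB medium at days 14 and 30. At day 7 the changes were shared between media. Of the 161 probes that changed at least 2-fold in both, 160 did so in the same direction, against 5.33 expected of independent lists, and the log2 changes correlated across probes with r = 0.604 (0.54 within array code 12; probes are not independent replicates). At day 14, 901 of 1151 shared probes moved in opposite directions (r = -0.28), and at day 30, 123 of 249 did (r = 0.12). The same direction was shared by 250 probes at day 14, against 288 expected of independent lists, and by 126 at day 30, against 20.1. At day 30 this excess came with directions split almost evenly, so independent lists are a low baseline for sharing. On the line from undifferentiated to day 90, groups with Matrigel differed from those without by a mean of 0.0368 ± 0.110 (SD, 6 pairs, 3 higher and 3 lower; exact two-sided sign-flip test, p = 0.438, adjusted over 2 tests 0.438, smallest possible 0.0313).

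BCM and EB medium differed at least 2-fold for few probes at day 7 and for many at days 14 and 30. Without Matrigel, 129 probes differed at least 2-fold at day 7, 2158 at day 14 and 2787 at day 30, and with Matrigel 66, 4023 and 3280 did. With no minimum fold, limma called 1838, 8640 and 10624 probes without Matrigel and 3279, 12046 and 11368 with it. At day 30 the difference was shared, since 1542 of 1601 probes in both lists had the same direction (r = 0.677 across probes). Independent lists, a low baseline as for Matrigel, would give 251. At day 14, 856 of 1044 had opposite directions (r = -0.324), and BCM at day 14 was the dim group. Averaged over 6 pairs, 254 probes differed at least 2-fold (122 higher and 132 lower in BCM), or 519 without day 14, and limma called 12027 with no minimum fold (6288 and 5739), or 10299 with the array code as a block. The split was 7712 higher and 3951 lower under median scaling, and 5279 and 6323 under cyclic loess. With the 6 pair differences as replicates limma called 0 probes, with 1710 at an unadjusted p under 0.05. Simulated 2-fold and 4-fold changes were recovered there in 36% and 72% of cases, again with few probes changed in the simulation. The difference had the same direction in all 6 pairs for 7.54% of probes, against 3.12% expected of 6 independent pairs. Pairs of the same day were not independent (r = 0.677 at day 30 and -0.324 at day 14), so the 3.12% is not a firm baseline. Of the 32 ways to turn the direction of pairs, 4 called at least as many probes as the real one and 11 at least as many of 2-fold or more (highest other 517). Within single array codes, 125 (day 7), 2420 and 2239 (day 14) probes differed at least 2-fold without Matrigel, and 79 and 104 (day 7), 3312 and 3345 (day 30) with it. No code held both groups without Matrigel at day 30 or with Matrigel at day 14, so these differences could not be taken within a code. Medium and code are separated there only through other groups that span codes. BCM groups lay lower on the line to day 90 in 4 of 6 pairs, by a mean of -0.113 ± 0.181 (SD), which the exact two-sided sign-flip test did not separate from 0 (p = 0.188, adjusted 0.375). At day 30 the differences were -0.185 without and -0.422 with Matrigel, at day 14 -0.142 and 0.0877, and at day 7 0.00175 and -0.0179.

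The effect of Matrigel differed between media for the most probes at day 14, where BCM was the dim group, outside the others in 3 of 5 array measures, and EB medium with Matrigel lay wholly in array code 59. The interaction of medium and Matrigel, averaged over 3 days, gave 1178 probes at least 2-fold (508 positive and 670 negative) and 9199 with no minimum fold (5267 and 3932), or 10339 with the array code as a block. The split was 3932 positive and 4981 negative under median scaling, and 4318 and 4388 under cyclic loess. By day, 306 probes had an interaction of at least 2-fold at day 7, 5892 at day 14 and 1790 at day 30. Without day 14 the averaged count was 4502, of which 452 were at least 2-fold. With the 3 daily interactions as replicates limma called 0 probes, with 206 at an unadjusted p under 0.05, fewer than that threshold gives by chance. That test recovered 0% of simulated 4-fold changes, but few probes were changed in the simulation, which makes the adjustment stricter. The 0% therefore cannot account for the 0 calls. The interaction had the same direction at all 3 days for 22.5% of probes, against 25% expected of independent days.

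At day 90, the groups with and without Matrigel in EB medium differed in more probes than the 2 media did with Matrigel. With Matrigel, 2840 probes differed at least 2-fold from EB medium alone (1508 higher and 1332 lower; 2787 within array code 59), of 10829 called by limma (5396 and 5433, or 5779 and 5157 under cyclic loess; 11699 with the array code as a block). Between BCM and EB medium, both with Matrigel, 571 differed at least 2-fold (373 higher and 198 lower in BCM; 681 and 589 within array codes 50 and 53), of 5539 called (2826 and 2713; 7040 with the array code as a block, 3458 higher and 3582 lower). The last count was 3598 without array 50A of BCM with Matrigel and 3213 when the fit held only the groups compared. The Matrigel effect in EB medium at day 90 differed from that at day 7 by at least 2-fold for 3599 probes (1767 higher and 1832 lower), of 10017 called (5111 and 4906), or 11534 with the array code as a block. All 3 comparisons rest on 2 or 3 arrays per group at day 90.

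The single arrays of day 60 have no replicate and no test. EB medium stood at 0.893 and EB medium with Matrigel at 0.878 on the line to day 90. Relative to undifferentiated cells, 6722 and 6598 probes were at least 2-fold apart.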

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

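In this part the count of splits for the interaction was planned before its result was seen, and all tests of the other 2 patterns were chosen after the result was seen.

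By tests of the difference itself, whose error is the spread between these arrays, the effect of Matrigel differed between media and between days. The interaction of medium and Matrigel called 9199 probes over 3 days, and 1989 at day 7, 11677 at day 14 and 6606 at day 30. It had the same direction at all 3 days for 22.5% of probes, against 25% expected of independent days. The Matrigel effect in EB medium at day 90 differed from that at day 7 for 10017 probes. Permuting the groups among arrays within each day gave the interaction a count as large in 1 of 100 splits, the real one. The count was 9042 probes in a fit of these arrays, against a highest other of 618. Permuting breaks up close replicates and so raises the residual spread, with or without an interaction. The splits thus show only that arrays of a group resemble each other, and cannot decide whether the interaction is real. They say nothing of differences between single cultures, since replicates may share a culture.

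EB medium with Matrigel at day 14 lay apart from the other groups, with 597 probes at least 2-fold above every other group, where the next group, EB medium at day 90, had 135. All 3 arrays carry array code 59, and the other 3 arrays of that code were displaced from their group mates in this direction by a mean of 4.25% of the distance (3.27% to 5.09%), which argues against the code as the cause. In 0 of 5 measures of brightness and background did the group lie outside the other groups, which argues against dim or bright arrays, and BCM at day 14 did in 3 of 5. Exchanged labels are not excluded, since the 597 probes stay the same when the labels of 2 whole groups are exchanged, and an earlier form of this test, a distance to the nearest group over 3 times the largest distance between replicates, was not met (0.875 against 0.377 log2 units). That this culture, or Matrigel in EB medium at this stage, differed remains a hypothesis, and culture and condition cannot be separated without a second culture.

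BCM groups lay nearer to undifferentiated cells than EB medium groups at day 30, by a mean of 0.304 of the distance to day 90; day 14 was dropped from this pattern once its differences were seen to go both ways (-0.142 and 0.0877). All BCM arrays of that day carry array codes 13 and 09, and within the groups that span these and other codes the difference was -2.55% of that gap, which argues against the codes. Array brightness, from its slope within groups, accounted for -0.974% of the gap (95% interval -2.13% to 0.179%), which argues against dimmer arrays. A slower course in BCM is a hypothesis that these values leave open, beside differences between single cultures. At day 90 the group in BCM with Matrigel was at 0.989, but it is among the groups whose mean defines 1, so this value cannot show whether BCM caught up. BCM without Matrigel was not analysed here after day 30.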

How the results depend on the processing

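Group means as replicates and the comparisons without single groups or days were chosen after seeing the data. Over the alternatives to value, filter, variance model and block, the counts with no minimum fold stayed within 1.5 times the values reported, except 3213 for BCM against EB medium at day 90 with only the groups compared and 4502 for the interaction without day 14 (fewer groups enter). With group means as replicates the counts were 4436 (day 14), 8312 (day 30) and 9776 (day 90 against undifferentiated cells), 4634 (day 30 against day 7) and 0 for day 90 against day 30, Matrigel, BCM and the interaction. The first 3, and the count of 10817 at day 7, share the undifferentiated mean, whose error does not enter. This test has fewer replicates and takes the spread between conditions as error.

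Leaving out 1 array gave 10776 to 11833 (day 7), 12097 to 13148 (day 14), 12980 to 13991 (day 30) and 14202 to 14933 (day 90 against undifferentiated cells), 14525 to 14840 (day 30 against day 7), 13041 to 13608 (day 90 against day 30), 9248 to 9731 (Matrigel), 11554 to 12277 (BCM), 8818 to 9260 (interaction), 9218 to 11001 (Matrigel at day 90), 3598 to 5707 (BCM at day 90, lowest without array 50A of BCM with Matrigel) and 8933 to 10184 (Matrigel at day 90 minus day 7). The lone array left in a group of 2 is then assumed to vary like the other groups. Positions on the line gave 0.0350 to 0.0386 for Matrigel and -0.115 to -0.110 for BCM.

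Counts of at least 2-fold depend on how low signals are treated. In the order day 7, 14, 30 and 90 against undifferentiated cells, day 30 against 7, day 90 against 30, Matrigel, BCM, interaction, Matrigel at day 90, BCM at day 90 and Matrigel at day 90 minus day 7, the authors' values gave 448, 776, 1199, 2885, 914, 913, 16, 40, 351, 940, 134 and 1221, against 1944, 2749, 3779, 6595, 3025, 2598, 76, 254, 1178, 2840, 571 and 3599. No background correction gave 1015, 1603, 2407, then 1856, 1699, 34, 127, 698, 1778, 312 and 2301 for all but day 90 against undifferentiated cells. An offset of 50 gave 1142 (day 7), 1740 (day 14), 2008 (day 30 against day 7), 39 (Matrigel), 137 (BCM), 745 (interaction) and 348 (BCM at day 90). BeadStudio background subtraction gave 169 (Matrigel), 441 (BCM) and 863 (BCM at day 90). An offset, a missing correction and the transformation compress low signals by construction. The 4 named probes kept direction and call in all alternatives.

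The replicate block on the authors' values called 11706, 12904, 13730, 14789, 14806, 13437, 9834, 11255, 9309, 10665, 5400 and 10011 probes in that order and changed no count by over 1.5 times. The numbers do not pair the samples, since residuals of same-numbered arrays correlated above 0.1 in 38.8% of 268 pairs. Arrays sharing a code correlated above 0.1 in 67% of 88 pairs. Array weights stopped before full convergence. Gene list tests and the replicate block on raw intensities were not run, for lack of gene names and of replicate numbers.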

Other observations

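In this part the test of array codes and the counts of splits were planned before their results were seen, and the other tests were chosen afterwards.

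Matrigel effects of different days were unrelated on average, with a mean correlation across probes of 0.00509 over 18 pairs. Single pairs ran from -0.25 (BCM at days 14 and 30) to 0.135. Noise between arrays is argued against, since estimates of one effect from separate arrays correlated at 0.785 or more. An earlier bound, that noise make up under 20% of the variance of every effect, was missed by BCM at day 7 with 21.4% and was replaced by this test. With the array code as a block the mean correlation changed by 0.00139, which argues against the codes. Exchanged labels of BCM with and without Matrigel at day 14 would raise the mean correlation of that effect with the other 6 by 0.133, too little to decide. By distance between means, EB medium with Matrigel at day 14 lay nearest to BCM at day 14, and EB medium to BCM with Matrigel. The groups nearest to these 2 BCM groups were of other days. An exchange within EB medium was not tested, so exchanged labels at day 14 remain open. Differences between single cultures cannot be told apart from Matrigel, since same-day effects in the 2 media correlated at 0.604 at day 7 but at -0.28 at day 14.

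Turning the direction of group pairs asked whether the averages over 6 pairs exceed those of arbitrary pairings. For Matrigel, 18 of the 32 patterns called at least as many probes as the real one (9623, highest other 10925), and for BCM against EB medium 4 of 32 did (12027, highest other 12396). Each turned pattern is itself a contrast of real group differences, so these ranks cannot decide whether either count is due to chance. They show only that neither average called more probes than all other contrasts of its pairs. For the time comparisons, splits of the same arrays did not reach the real count except the real split itself. In 2-group fits, 1 of 100 splits gave as many probes at day 7 (8919, highest other 1669), day 14 (5804, highest other 2), day 30 (8959, highest other 3967) and day 90 (11409, highest other 1) against undifferentiated cells. Day 30 against day 7 (13263, highest other 6618) and day 90 against day 30 (9347, highest other 5812) also gave 1 of 100, with days permuted within conditions. These splits mix close replicates of different groups, which raises the residual spread and lowers the other counts. For these 6 counts they show only that arrays of the same group or day resemble each other. They say nothing of differences between single cultures.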
